A study of Mus musculus with 5 samples.

How the data were processed

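Total RNA from the brain of 5 male C57BL/6 mice aged 30 months was made into libraries with an Illumina multiplexed mRNA preparation kit and sequenced, per the labels' protocols. The authors deposited whole-number counts per gene for 47729 Ensembl genes in each of the 5 libraries. Per the submitters' processing notes, CASAVA 1.7, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with the GRCm38 genome; the notes give no role, order or settings for them. The annotation release, the strand setting and any filters on reads were not given in the sources used here, so reads from overlapping or antisense genes, and from near-identical copies, cannot be assigned with certainty. The authors also deposited RPKM values (counts divided by gene length and library total) for the same genes and libraries. Every per-sample column was used.

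The deposited RPKM were checked against the deposited counts. Among 12729 genes with at least 30 counts and a deposited RPKM of at least 0.3 in every library, the gene lengths implied by the 5 RPKM values were within 1% of each other for 0 genes when each library's own total was used. They were within 1% for all 12729 when the 5 library totals were taken in turn from gene to gene down the table. Only 20% of the RPKM values were therefore divided by their own library's total, and the deposited values lie between 0.821 and 1.22 times those recomputed with it. For the genes checked, the median ratio of the deposited to the recomputed SD was 1.13. Levels in RPKM are given after recomputing with each library's own total, a choice made after the data were examined; the number of genes detected and the gene pairs use the deposited RPKM, as fixed before.

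Gene identifiers were matched to GENCODE M21, which annotates GRCm38: 47224 genes had a symbol, and the unmatched ones held 0.0770% of counts. The implied lengths of 74.6% of the genes checked were within 1% of the M21 exon length, so the authors' annotation may be another release. Coordinates, GC content and gene types come from M21. The libraries held between 15392006 and 18723390 counts, and a count of 0 allows up to 3 counts. Intervals and such limits cover counting error only. Counts of every pair of libraries differed by far more than sampling noise (chi-square per gene from 6.97 to 102), so all 5 were kept as separate samples.

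Because the labels give a single group, there was no contrast between groups. Variation between mice was tested in edgeR 4.0.16 with quasi-likelihood fits of an intercept to the counts, with TMM scaling, for 16318 genes with a mean count of at least 10. Each gene's dispersion was compared with an F distribution fitted robustly along mean expression (limma 3.58.1), with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation is the square root of edgeR's common dispersion. Counts were simulated for the same 16318 genes, and the genes to be raised were drawn from those with a mean count of at least 100. This test recovered 19 of 100 genes raised 4-fold in 1 mouse and 100 of 100 raised 16-fold, with 4 false calls. Moderate differences in a single mouse would therefore mostly be missed, and recovery at lower counts was not measured. Both sets of 100 genes were raised in the same simulated counts, which makes the adjusted threshold easier to pass. Recovery of a few genes that vary alone was not measured and may be lower, also for large differences.

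A total of 54 gene lists with 691 distinct genes, of which 2 had no match, was fixed before the data were examined: markers of cell types and brain regions, and genes of immune, stress, metabolic and synaptic functions. For each list with at least 4 members at a mean count of at least 10, the SD over the mice of the mean log2 CPM (prior count 1) was ranked among 10000 random lists matched on size and on 20 bins of mean expression. Lists at or above percentile 99 were counted. This describes these libraries and is not a test over mice. Of lists of 12 genes drawn at random from the same data, 1 of 100 reached it, as the percentile gives by construction. When such lists were shifted by 1.5 log2 units in 1 mouse, 20 of 20 reached it. The 22 gene pairs were compared by the log2 ratio of RPKM with a pseudocount of 1, in an exact two-sided sign-flip permutation test over the 5 mice. Values of a mouse far from the other 4 were identified where the gap to the nearest value exceeded 0.71 of the range (Dixon's criterion for 5 values).

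Genes were named by a rule fixed before the data were examined. It takes the 20 genes with the highest mean deposited RPKM, up to 25 of the genes called variable, for each list any members called variable and those with the highest and the lowest mean RPKM (at most 4 in all), the 3 members with the largest SD of log2 CPM of lists at or above percentile 99, all pairs, and the Y-linked genes with Xist and Tsix. Some genes and pairs that the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen.

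Alternatives fixed in advance were DESeq2 (1.42.0) size factors and dispersion outliers, library size scaling, no count filter or a mean of at least 50, a prior count of 5, a non-robust prior, limma on log2 RPKM with pseudocounts of 1 and 0.1, RPKM limits, counts without length correction, and leaving out each mouse. Chosen after the data were examined were the recomputed RPKM, protein-coding genes only, random lists of protein-coding genes, lists without the genes that another list also holds, and removing from each library its trend over GC content and log2 length (natural splines with 5 and 3 degrees of freedom), with or without mouse 11. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. No correlation across samples is given, since there are only 5.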

Results

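RNA sequencing was used to measure gene expression in the brain of 5 male mice of the inbred laboratory strain C57BL/6 at an age of 30 months. All 5 samples belong to 1 group and are named here by their label numbers, as mice 7, 8, 9, 10 and 11. The libraries held 15549967, 15392006, 15665819, 16044378 and 18723390 counts in that order, and between 22686 and 24708 genes had at least 1 count in a library. No other age, sex or tissue was analysed here, so the design asks which genes were expressed in the brain at this age, at what level, and how far the mice differed. Errors are SDs over the 5 mice (n = 5 throughout). The labels give sample numbers and speak of animals in the series title only, so SDs and p-values measure the spread between these samples, which may in part be technical.

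The most abundant RNAs of the brain came from the mitochondrial genome and from genes of iron storage, peptide processing, calcium signalling and energy supply. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 reached 7221 ± 1914 and 7221 ± 1438 RPKM (reads per kilobase of transcript, scaled to library size). The respiratory chain subunits mt-Co1 and mt-Cytb followed with 4293 ± 317 and 3510 ± 162 RPKM, and mt-Nd2, mt-Nd6, mt-Nd1, mt-Nd5 and mt-Nd4 lay between 1341 and 2870 RPKM. The most abundant protein-coding nuclear genes were Fth1, the ferritin heavy chain that stores iron, at 2149 ± 292 RPKM, and Cpe, the carboxypeptidase that trims neuropeptides, at 1362 ± 156 RPKM. Calm2 (calmodulin), Psap (prosaposin, a lysosomal protein precursor), Sparcl1 (a matrix protein secreted by astrocytes), App (the amyloid precursor protein), Atp1b1 (a sodium pump subunit) and Ckb (brain creatine kinase) lay between 574 and 661 RPKM. The processed pseudogenes Gm12328, Gm37421 and Gm44389 were also among the 20 highest, at 2067, 1634 and 709 RPKM; their reads may be shared with their parent genes, so these levels are uncertain. Together the 20 genes with most counts in each library took 7.35% ± 0.477 of the counts, mitochondrially encoded genes 4.28% ± 0.428 and protein-coding genes 96.8% ± 0.421. The mitochondrial share and the levels of mt-Co1 and mt-Nd4 may be too low, since parts of the mitochondrial sequence also occur in nuclear transcripts. A mean deposited RPKM of at least 1 was reached by 13164 genes.

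Markers of neurons, glia, vessels and choroid plexus were all measured. Snap25, a protein of synaptic vesicle fusion, had 298 ± 50.3 RPKM and the RNA-binding protein gene Elavl4 17.0 ± 0.584 RPKM. Among excitatory neuron markers the vesicular glutamate transporter Slc17a7 had 348 ± 101 RPKM, with 520 in mouse 11 and 271 to 339 in the others, and the transcription factor Rorb 4.89 ± 1.15. Among inhibitory neuron markers the peptide somatostatin (Sst) had 173 ± 61.6 RPKM, with 280 in mouse 11, and Dlx2 1.18 ± 0.423. The astrocyte glutamate transporter Slc1a2 had 305 ± 55.7 RPKM and Sox9 8.69 ± 2.84. Myelin basic protein (Mbp) had 346 ± 73.2 RPKM and the oligodendrocyte enzyme Aspa 3.83 ± 1.4, while the precursor markers Olig1 and Bmp4 had 48.8 ± 13.7 and 0.836 ± 0.189. The microglial protease Ctss had 69.1 ± 6.68 RPKM and Fcrls 1.31 ± 0.546. The endothelial glucose transporter Slc2a1 had 35.2 ± 9.52 RPKM and Emcn 0.889 ± 0.206, and the mural cell markers Vtn and Higd1b 38.7 ± 5.02 and 1.43 ± 0.439. Transthyretin (Ttr), the main secreted protein of the choroid plexus, had 404 ± 70.5 RPKM and Prlr 0.661 ± 0.329. Igf2 and Col3a1, markers of meningeal fibroblasts, had 15.3 ± 2.57 and 0.409 ± 0.0701 RPKM. The ependymal marker Tmem212 had 2.50 ± 0.881 RPKM and Mia a mean of 0.4 counts. Tubb2b and Ccnb1, of the neuroblast and dividing cell list, had 22.0 ± 1.57 RPKM and a mean of 1 count.

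To ask whether groups of genes fixed in advance differed between the mice together, the SD over the mice of each list's mean log2 CPM was placed among 10000 random lists of the same size and expression. Of 52 lists with at least 4 measured members, 17 reached percentile 99. Lists drawn at random reach it about 1 time in 100 by construction, and 1 of 100 drawn here did. That is no error rate for lists of related genes, which may vary together for any reason. Among the cell types above, none reached it: excitatory neurons were at percentile 98.1, inhibitory neurons at 98.9, oligodendrocytes at 98.4, their precursors at 89.3, ependyma at 87.0, astrocytes at 81.3, choroid plexus at 78.0, mural cells at 77.2, meningeal fibroblasts at 69.1, neuroblasts and dividing cells at 65.2, microglia at 40.8, endothelium at 27.6 and all neurons at 23.9. Leaving out mouse 7 brought excitatory neurons to 99.09, inhibitory neurons to 99.29 and oligodendrocytes to 99.25. Leaving out mouse 9 or 10 brought inhibitory neurons to 99.05 or 99.02, and leaving out mouse 11 brought oligodendrocytes to 99.97 but excitatory and inhibitory neurons to 58.6 and 48.5. Without genes of other lists, excitatory neurons, then with 4 members, were at 99.99 (97.9 with trends also removed) and inhibitory neurons at 94.7. Oligodendrocytes were at 92.0 without mouse 9 and 63.8 with deposited RPKM. They were also at 99 with DESeq2 size factors, 99.44 with library size scaling, 99.36 at a mean count of at least 50, 99.33 with recomputed RPKM and 99.67 with the GC and length trends removed and mouse 11 left out.

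**Figure D1:**
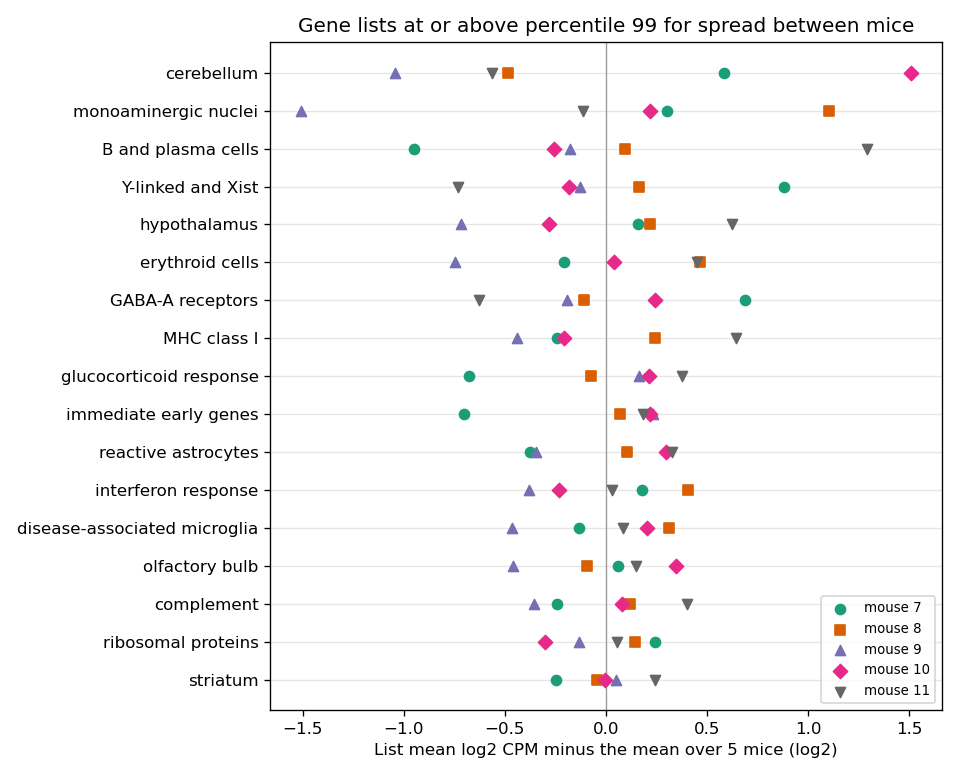
Log2 deviation of each mouse from the mean of the 5 mice (horizontal axis, log2 CPM units) for the 17 gene lists at or above percentile 99, with 1 point per mouse. The cerebellum list ranged from -1.04 in mouse 9 to 1.51 in mouse 10.

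Genes marking the cerebellum and the monoamine-producing nuclei differed most between the mice. The cerebellum list was at percentile 100, with mean log2 deviations of 0.58, -0.49, -1.04, 1.51 and -0.57 in mice 7 to 11, and 10 of its 15 members were highest in mouse 10. Cbln3, which encodes a secreted synaptic protein of cerebellar granule cells, had 5.16 RPKM in mouse 10 and 0 to 1.24 RPKM in the others. Fat2, a cadherin of the same cells, had 2.74 RPKM in mouse 10 and 0.0331 to 0.708 in the others, from 638 counts against 9 to 160. Gabra6, a GABA-A receptor subunit of granule cells, had 52, 2, 0, 127 and 0 counts, where a count of 0 allows up to 3 counts. Pcp2, a Purkinje cell gene, had 1.88 RPKM in mouse 10 and 0.0877 to 0.563 in the others. Pvalb, also expressed by many forebrain interneurons, had 59.4 ± 8.74 RPKM. In the GRCm38 genome Cbln3 (ENSMUSG00000040380) is a protein-coding gene on chromosome 14 from 55878913 to 55884392. Fat2 (ENSMUSG00000055333) and Gabra6 (ENSMUSG00000020428) are protein-coding genes on chromosome 11, from 55250609 to 55336564 and from 42306437 to 42321072.

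The monoaminergic list was also at percentile 100, with deviations of 0.30, 1.10, -1.51, 0.22 and -0.11 in mice 7 to 11. Of its 10 measured members 6 were highest in mouse 8 and 7 lowest in mouse 9. Tph2, the rate-limiting enzyme of serotonin synthesis in neurons, had 7.51 RPKM in mouse 8 and 0.288 in mouse 9, and the serotonin transporter Slc6a4 had 3.33 and 0.127. Dbh, which makes noradrenaline, had 0.286 ± 0.282 RPKM, Aldh1a1, found in a subset of dopamine neurons, 21.6 ± 7.17 and Pitx3 a mean of 2 counts. Tph2 (ENSMUSG00000006764) spans 115078641 to 115185022 on chromosome 10, and Slc6a4 (ENSMUSG00000020838) 76998603 to 77032340 on chromosome 11.

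The hypothalamus, olfactory bulb and striatum lists were also above percentile 99. The hypothalamus list, at 99.99, had deviations of 0.16, 0.22, -0.72, -0.28 and 0.62. Removing the GC and length trend of each library took its SD from 0.51 to 0.32 and its deviation in mouse 11 to 0.25. Its neuropeptide genes vasopressin (Avp), orexin (Hcrt) and oxytocin (Oxt) had 12.2 ± 10.5, 4.46 ± 3.65 and 2.32 ± 1.58 RPKM; each was highest in mouse 11 and lowest in mouse 9, and Npvf had a mean of 0.6 counts. The olfactory bulb list, at 99.3, was lowest in mouse 9 (-0.46), where Th, the rate-limiting enzyme of catecholamine synthesis, had 1.94 RPKM against 5.14 to 7.91; Nrsn1 had 175 ± 10, Lhx1 0.690 ± 0.424, Eomes 0.368 ± 0.198 and Tbx21 0.138 ± 0.0213 RPKM. Without mouse 9 or mouse 10 this list was at percentile 83.7 or 97.1, and it was at 87.0 at a mean count of at least 50, 94.9 with deposited and 93.6 with recomputed RPKM, 98.84 with library size scaling and 95.2 without genes of other lists (98.1 with trends also removed). The striatum list was at 99.4, and 11 of its 15 members were lowest in mouse 7. Its dopamine signalling protein gene Ppp1r1b had 59.0 ± 16.9 RPKM, the phosphodiesterase Pde1b 121 ± 13.8, Syndig1l 14.6 ± 3.16 and the receptor Gpr6 5.32 ± 1.16. The striatum list was at 94.1 without mouse 7, 98.2 without mouse 8 and 96.3 once the GC and length trends were removed. It was at 97.89 with DESeq2 size factors, 96.57 with library size scaling, 98.72 at a mean count of at least 50, 97.69 with deposited and 97.6 with recomputed RPKM.

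The remaining region lists stayed below percentile 99. Cortex was at 95.4, with the presynaptic gene Stx1a at 61.0 ± 12.7 RPKM and Emx1 at 3.50 ± 1.15, thalamus at 80.1, with calretinin (Calb2) at 43.8 ± 8.94 and Gbx2 at 0.837 ± 0.216, and hippocampus at 49.9, with Wfs1 at 47.0 ± 7.88 and Tdo2 at 0.369 ± 0.218. Pituitary was at 74.9, with Chga at 61.0 ± 11.7 RPKM and the hormone subunit Cga at 0 counts in every library, and retina and muscle at 29.7, with Acta1 at 3.67 ± 0.792 and Ckm at a mean of 0.6 counts. The brainstem and spinal cord list had only 2 measured members and was not tested; Chat, the enzyme of acetylcholine synthesis, had 1.67 ± 0.306 RPKM and Hoxb3 a mean of 0.2 counts.

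Of the lists of blood-derived and lymphoid genes, those of erythroid cells and of B and plasma cells were above percentile 99. The erythroid list, at percentile 100, had deviations of -0.21, 0.46, -0.75, 0.04 and 0.45 in mice 7 to 11, with 0.28 in mouse 11 once the GC and length trends were removed. The haemoglobin genes Hba-a1 and Hba-a2, near-identical copies whose reads may be split between them, had 36.7 ± 20.1 and 30.7 ± 14.0 RPKM, with 12.9 and 13.7 in mouse 9 against 62.0 and 46.2 in mouse 11. The anion exchanger gene Slc4a1 had 0.204 ± 0.126 RPKM. The B and plasma cell list, at 99.9, had all 5 measured members highest in mouse 11. The antibody light chain gene Igkc had 12.6 RPKM there and 3.02 to 4.57 in the others, and the heavy chain genes Ighg2b and Igha had 0.369 ± 0.473 and 0.293 ± 0.275 RPKM. Ighm had 9.17 ± 1.48 RPKM and Ms4a1 a mean of 0.6 counts. Without mouse 11 this list was at 95.4, and at 95.1 with the trends also removed. T cells were at 90.8, with Trbc2 at 4.49 ± 0.632 RPKM and Cd3d at a mean of 1.2 counts. Neutrophils and monocytes were at 98.3, at 75.9 without mouse 8, where they were highest (0.83), at 99.22 and 99.49 without mouse 7 and mouse 11, at 99.88 and 99.7 with deposited and recomputed RPKM, at 99.32 with the trends removed and mouse 11 left out and, without genes of other lists, at 99.32 and, with trends also removed, 99.41, with S100a9 at 1.68 ± 0.998 RPKM and Mpo at a mean of 3.8 counts.

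Genes of antigen presentation, complement and glial activation differed between the mice, and 3 of the 4 lists were lowest in mouse 9. MHC class I, at percentile 100, had deviations of -0.24, 0.24, -0.44, -0.21 and 0.64, with 10 of 12 members highest in mouse 11. With the GC and length trends removed mouse 11 was at 0.42, with 7 members highest there. With the trends kept, mouse 11 was also highest for 11 of 20 lysosomal and 11 of 15 synaptic vesicle genes, lists below percentile 99. It was highest for 1 of 13 GABA-A receptor genes. The MHC class I light chain B2m had 188 ± 40.2 RPKM, the peptide transporter Tap1 1.68 ± 0.661 and the regulator Nlrc5 0.405 ± 0.160. H2-Q7, one of a family of close copies and so uncertain, had 0.985 ± 0.918 RPKM. The complement list, at 99.8 (98.8 without mouse 9), ranged from -0.35 in mouse 9 to 0.40 in mouse 11, or 0.23 with the trends removed. C1qb and C1qc, chains of the first complement component, had 55.1 ± 14.1 and 20.5 ± 8.70 RPKM, C2 0.491 ± 0.256, C5ar1 0.490 ± 0.216 and Cfb a mean of 2.8 counts. The disease-associated microglia list, at 99.99 (96.7 without mouse 9 and 98.27 at a mean count of at least 50), ranged from -0.47 in mouse 9 to 0.31 in mouse 8. Its lipid carrier Apoe had 292 ± 95.8 RPKM, the cystatin Cst7 2.25 ± 1.49, with 4.41 in mouse 8 and 0.583 in mouse 9, osteopontin (Spp1) 9.01 ± 5.07 and the receptor Clec7a 0.909 ± 0.514. Reactive astrocyte genes, at 99.99 (97.0 without genes of other lists), had deviations of -0.38, 0.10, -0.35, 0.30 and 0.33. The protease inhibitor Serpina3n had 22.6 and 22.9 RPKM in mice 7 and 9 and 37.7 to 55.6 in the others. The intermediate filament Gfap had 115 ± 24.4 RPKM, the iron-binding protein Lcn2 1.31 ± 1.11, the small chaperone Hspb1 4.25 ± 1.98 and Cxcl10 0.414 ± 0.101.

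Interferon response genes, at percentile 99.7, ranged from -0.38 in mouse 9 to 0.41 in mouse 8, and were at 92.9 without mouse 8, 97.5 without mouse 9 and 93.7 at a mean count of at least 50. The antiviral genes Ifit1 and Ifit3 were highest in mouse 7, at 2.28 and 6.60 RPKM, against 0.402 to 2.03 and 1.5 to 4.47 in the others. Ifi27 had 15.1 ± 2.27 RPKM, Irf7 0.871 ± 0.334 and Ifi44 0.143 ± 0.0539. MHC class II was at 97.6, at 72.8 without mouse 11, at 59.8 with the trends also removed, at 99.61 without mouse 7, at 99.58 for a mean count of at least 50 and at 99.97 and 99.42 with deposited and recomputed RPKM, with Cd80 at a mean of 4.6 counts. Senescence and secretory genes were at 72.7, with the lysosomal galactosidase Glb1 at 12.1 ± 0.557 RPKM and Il6 at a mean of 2 counts.

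Genes induced by neuronal activity and by glucocorticoids had their lowest values in mouse 7. The immediate early gene list, at percentile 100, had deviations of -0.70, 0.07, 0.23, 0.22 and 0.18 in mice 7 to 11, and 13 of 15 members were lowest in mouse 7. With the GC and length trends removed the deviations of mice 7 and 11 were -0.58 and -0.19. The transcription factor Egr1 had 34.6 RPKM in mouse 7 and 56.3 to 75.2 in the others, Egr2 0.530 against 1.51 to 2.97 and Egr4 2.4 against 3.72 to 9.35. Arc, a regulator of synaptic receptors, was an exception, with 17.2 RPKM in mouse 11, 19.8 in mouse 7 and 42.5 to 58.9 in the others. Without mouse 7 this list was at percentile 61.2. The glucocorticoid response list, at 100, had deviations of -0.68, -0.07, 0.16, 0.21 and 0.38, with 11 of 13 members lowest in mouse 7, and was at 98.4 without that mouse. The kinase Sgk1 had 14.6 RPKM in mouse 7 and 26.8 to 45.0 in the others, and the lipid droplet gene Plin4 0.534 against 0.9 to 2.29. The metallothionein Mt1 had 204 ± 62.3 RPKM. Sgk1 (ENSMUSG00000019970) lies on chromosome 10 from 21882184 to 21999903 and Arc (ENSMUSG00000022602) on chromosome 15 from 74669083 to 74672570.

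**Figure D2:**
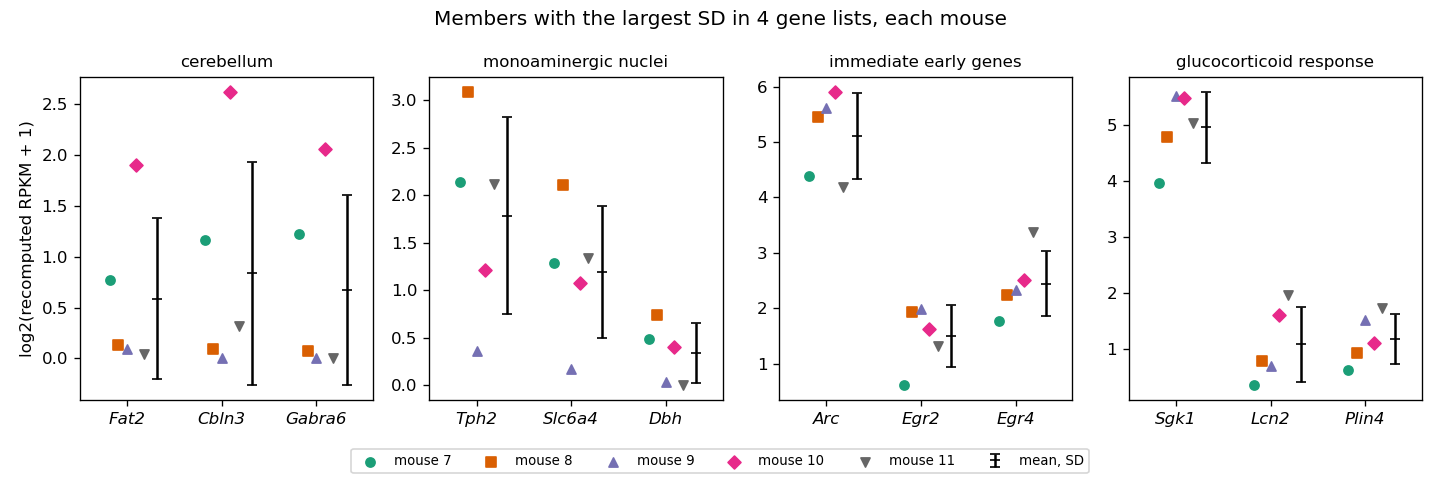
Expression as log2(RPKM + 1) in each mouse (vertical axis; each panel has its own scale) for the 3 members with the largest SD in 4 gene lists, with 1 point per mouse, a tick at the mean and a bar for the SD (n = 5). Fat2, Cbln3 and Gabra6 were highest in mouse 10, Tph2 and Slc6a4 in mouse 8, and Egr2 and Sgk1 were lowest in mouse 7.

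The lists of GABA-A receptor, ribosomal protein and Y-linked genes had their highest mean in mouse 7. The GABA-A receptor list, at percentile 100, had deviations of 0.69, -0.11, -0.19, 0.24 and -0.63, with 10 of 13 members highest in mouse 7. With the GC and length trends removed its SD went from 0.49 to 0.29, mouse 7 was at 0.35 and mouse 11 at -0.26, and 6 members were highest in mouse 7. Gabra6, also in the cerebellum list, had the largest SD of its members. Without Gabra6 the list stayed at percentile 100 (SD 0.34, with 0.50 in mouse 7, -0.080 in mouse 10 and -0.44 in mouse 11), but with the trends also removed it was at 88 (SD 0.10). The subunits Gabrb1 and Gabrg1 had 20.1 and 5.70 RPKM in mouse 7 and 6.49 and 1.87 in mouse 11. Ribosomal protein genes, at 99.99, had deviations of 0.24, 0.14, -0.13, -0.30 and 0.05, with 8 of 20 members highest in mouse 7, 7 in mouse 8 and 5 in mouse 11, and Rpl5 at 16.5 RPKM in mouse 7 and 4.88 to 7.79 in the others. Rpl37 had 45.0 ± 16.5 RPKM and Rps4x 44.7 ± 17.3; these genes have many pseudogene copies, so their counts are uncertain. That list was at 98.55 without mouse 10 and at 89.7 with the deposited RPKM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 6.33 ± 5.18, 7.12 ± 2.57, 1.58 ± 0.540 and 2.07 ± 0.708 RPKM in these male mice, while Xist and Tsix had means of 5.2 and 1.4 counts. The Y-linked list was at 99.99, and at 98.4 with the GC and length trends removed (98.27 without mouse 11 as well), when its SD went from 0.59 to 0.24.

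The remaining metabolic, synaptic and disease gene lists were below percentile 99. Synaptic vesicle genes were at percentile 97.2, at 99.27 without genes of other lists and 61.5 with deposited RPKM, with Cplx1 at 338 ± 59.0 RPKM and Synpr at 13.9 ± 2.43. Glutamate receptors were at 98.7, at 99.52 and 99.42 without mouse 8 and mouse 11, at 99.57 and 99.56 with DESeq2 and library size scaling, at 99.4 for a mean count of at least 50, and at 99.75 with recomputed RPKM, but at 38.0 with deposited RPKM, 91.6 without mouse 7, 53.7 with the GC and length trends removed and 32.6 with mouse 11 also left out, with Gria1 at 87.6 ± 7.20 and Grin2d at 4.13 ± 1.15. The nuclear respiratory chain was at 95.8, at 99.91 without mouse 11, 70.2 without mouse 10 and 28.6 with deposited RPKM, with Atp5a1 at 327 ± 9.26 and Ndufs1 at 13.2 ± 2.92. Lysosomal genes were at 98.3 (Lamp1 211 ± 17.9, Tfeb 1.09 ± 0.496), antioxidant genes at 96.7 (Hmox1 2.89 ± 0.616), the unfolded protein response at 96.3 (Hspa5 61.1 ± 10.6, Trib3 0.431 ± 0.145), the circadian clock at 93.1 (Tef 63.9 ± 11) and hypoxia and glycolysis at 87.8 (Aldoa 335 ± 56.2, Adm 1.10 ± 0.315). Insulin and nutrient signalling was at 86.3 (Igfbp5 47.3 ± 4.54, Angptl4 0.420 ± 0.165), heat shock and chaperones at 76.2 (Hsp90ab1 538 ± 27.4, Hspa1a 1.20 ± 0.457), mitochondrially encoded genes at 73.2, neurodegeneration genes at 70.8 (App 613 ± 37.8) and cholesterol synthesis at 29.8 (Hmgcs1 95.7 ± 19.7, Fdps 0.781 ± 0.248). Replication histones had 2 measured members and were not tested; Hist1h2bc had 20.8 ± 5.70 RPKM and Hist1h2ae 0 counts. With the GC and length trends removed, mitochondrially encoded genes were at 99.94, the unfolded protein response at 99.42 and insulin and nutrient signalling at 99.02. With mouse 11 also left out these were at 99.49, 99.81 and 98.04, and antioxidant genes at 99.08. Over all settings the lowest percentiles of these 4 lists were 17.1, 62.3, 64.8 and 82.5. Removing the trends took the SD of the mitochondrially encoded list from 0.11 to 0.22, so the removal itself widened that spread.

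Related genes were also compared within each mouse, as 22 pairs fixed in advance, by the log2 ratio of deposited RPKM with a pseudocount of 1. The excitatory vesicular transporter Slc17a7 exceeded Slc17a6 by 4.51 ± 0.91, and the ubiquitous chaperone Hsp90ab1 exceeded the inducible Hsp90aa1 by 3.56 ± 0.89. Gfap exceeded Aldh1l1 by 2.93 ± 0.12, the cell cycle inhibitor Cdkn1a exceeded Cdkn2a, which had a mean of 2.8 counts, by 2.81 ± 0.51 (5.01 with a pseudocount of 0.1), B2m exceeded H2-K1 by 2.67 ± 0.19 and the light neurofilament Nefl exceeded the heavy Nefh by 2.29 ± 0.37. With recomputed RPKM the SDs of these last ratios were 0.32 and 0.19. Ratios between 0.68 and 1.97 were found for Slc1a2 over Slc1a3, Sod1 over Sod2, App over Aplp2 and Gad1 over Gad2. The ratio was negative in all 5 mice for the glutamate receptor genes Gria2 to Gria1 (-1.47 ± 0.49) and Grin2a to Grin2b (-0.97 ± 0.14), for the clock genes Dbp to Nr1d1 (-1.26 ± 0.64) and Per2 to Arntl (-0.77 ± 0.41) and for the metallothioneins Mt3 to Mt1 (-1.22 ± 0.60). In all, 17 of the 22 pairs had the same sign in 5 of 5 mice, which gave p = 0.0625 in an exact two-sided sign-flip permutation test over 32 arrangements, the smallest p that 5 mice allow, and a Benjamini-Hochberg adjusted p of 0.0809. No pair could therefore pass 0.05. Among the others, sign was shared by 4 of 5 mice for Drd2 to Drd1 (0.35 ± 0.40, positive in 5 of 5 mice with recomputed RPKM), Apoe to Clu (0.30 ± 0.28) and C1qa to C4b (0.12 ± 0.33), with exact permutation p from 0.125 to 0.4375.

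Gene by gene, the largest excess of variation over genes of similar expression belonged to the cerebellar genes Fat2 and Cbln3, but no gene passed the threshold. In edgeR's quasi-likelihood fit 0 of 16318 genes were called at an adjusted p of 0.05, 786 had an unadjusted p under 0.05, and the smallest adjusted p was 0.585. DESeq2 marked 49 genes as dispersion outliers, led by Cbln3, Gabra6 and Fat2, and limma on the deposited RPKM called 0 genes, with 623 at an unadjusted p under 0.05. With the GC and length trends removed and mouse 11 left out, edgeR called 2 genes, Fat2 and Cbln3, both at an adjusted p of 0.0323. The edgeR fit without a low-count filter called 230 of 28335 genes. The biological coefficient of variation, the typical spread beyond counting error, was 0.234, and 0.167 without mouse 11.

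**Figure D3:**
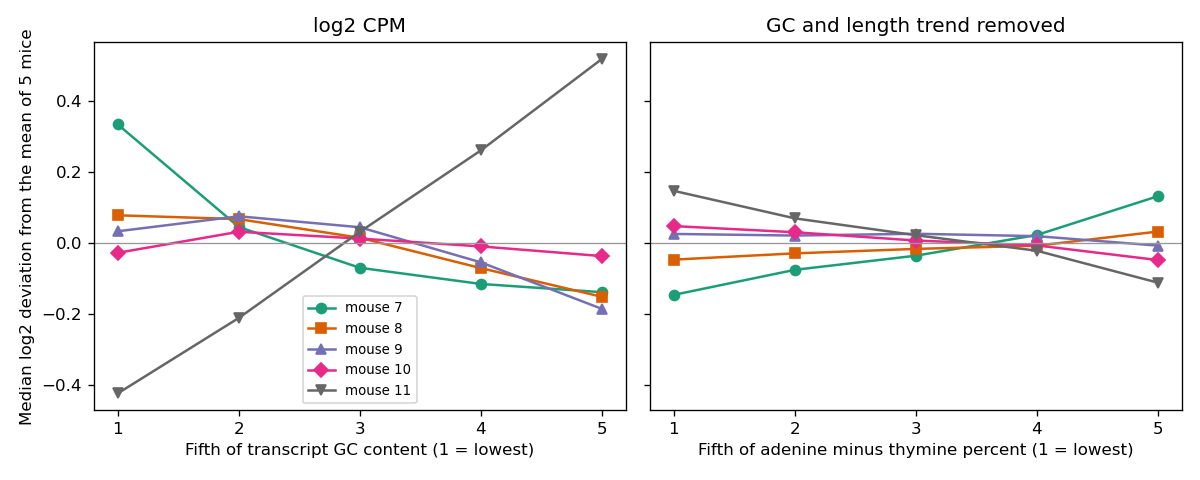
Median log2 deviation of each mouse (vertical axis) in 5 equal bins of genes (horizontal axis) ordered by transcript GC content (left) or, with the GC and length trends removed, by adenine minus thymine percent (right), with 1 line per mouse. By GC content mouse 11 runs from -0.42 to 0.52 and mouse 7 from 0.33 to -0.14, and by adenine minus thymine mouse 7 runs from -0.15 to 0.13.

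The libraries themselves differed along GC content and transcript length. These properties accounted for 43.9% of the variance of gene deviations in mouse 11, 20.8% in mouse 7 and 2.49% to 11.4% in the others. Mice 7 and 11 stood at the ends of the first principal component (scores -40.1 and 64.9), which held 52.0% of the variance and 40.5% once the trends were removed. With the trends removed 18 lists reached percentile 99, of which 15 were among the 17 above.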

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

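Of 248 values compared across the 5 mice, 29 had a single mouse far from the other 4. Chance gives about 1 in 20, or 12.4, if values are normally distributed. Single genes were compared as RPKM without logarithms, so the excess depends on the scale. Some of these genes were named for a large SD between these same mice, so the chance rate does not apply to them. Among the 24 flagged genes and ratios, 8 passed on a log2 scale after TMM scaling. Of the 29, 19 were in mouse 11, 6 in mouse 7 and 4 in mouse 10, and many of the values are not independent of each other. Chosen only after the results were seen were the GC and length tests of both patterns and all values with these trends removed; the tests of second tissue lists, of adenine content and of thinning were stated before their results were seen, but after the patterns that prompted them. The design gives no second group, so no biological explanation other than numbers of microglia was tested.

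In mouse 11 the library total was 18723390 against 15392006 to 16044378, and processed pseudogenes took 0.15% of counts (Wilson 95% interval 0.149 to 0.152) against 0.163% to 0.167%. Mean log2 deviations were 0.317 for excitatory neurons (others -0.129 to -0.0282) and 0.343 for inhibitory neurons (others -0.154 to -0.0388). With the GC and length trend of each library removed they were 0.25 and 0.14, and the gaps to the nearest mouse, 0.538 and 0.314 of the range, no longer passed 0.71. With recomputed RPKM the log2 ratio of Dbp to Nr1d1 was -0.242 (others -1.69 to -1.35). Higher than in the other mice were Slc17a7 at 520 RPKM, Sst at 280, Dlx2 at 1.91, Olig1 at 72.7, Ighg2b at 1.20, Igkc at 12.6, Stx1a at 83.4, Ppp1r1b at 88.2, Avp at 30.4, Aldoa at 434, Ckb at 877 and Dbp at 33.7. Lower were mt-Cytb at 3226 RPKM, against 3553 to 3638, and Arntl at 11.5, against 14.2 to 15.1. With the trends removed, of the single genes and the ratio in mouse 11 only Ighg2b, Igkc and the ratio of Dbp to Nr1d1 still passed 0.71. The log2 deviation of mouse 11 went from 0.68 to 0.29 for Slc17a7 and from 0.53 to 0.061 for Stx1a, and turned for Olig1 (0.67 to -0.020), Ckb (0.72 to -0.056) and mt-Cytb (-0.060 to 0.23); mt-Cytb and Arntl did not pass 0.71 after TMM scaling alone.

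In mouse 7 the immediate early gene list stood at -0.701 (others 0.0691 to 0.234). With the trends removed it was at -0.58, mouse 11 at -0.19, and the gap of 0.411 of the range no longer passed 0.71. Rpl5 had 16.5 RPKM, Ddx3y 15.3 and Hsp90aa1 115, against at most 7.79, 6.04 and 45.8 in the others. Cpe had 1086 RPKM and Aplp2 205, against at least 1405 and 249. Aplp2 did not pass 0.71 after TMM scaling, and Ddx3y did not with the trends removed. In mouse 10 Adm had 1.66 RPKM, against 0.914 to 1.

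Mouse 10 also had the highest values of the cerebellar genes Cbln3 (5.16 RPKM, others 0 to 1.24), Fat2 (2.74, others 0.0331 to 0.708) and Pcp2 (1.88, others 0.0877 to 0.563). A trend over GC content and length is argued against, since 99.1% of the SD of the cerebellum list was kept once it was removed. Different amounts of cerebellar tissue may contribute: a second list of 18 cerebellar markers, none in the first lists, stood at percentile 99.94 in mouse 10, with 9 members highest there, although mouse 7 was not raised on it (-0.12) and its most abundant members Etv1 and Cadps2 had 11 and 10.1 RPKM in mouse 10 against means of 10.8 and 10.1. Different amounts of hindbrain tissue may contribute to the monoaminergic value of mouse 8, where 13 measured genes of a second hindbrain list stood at percentile 99.83, with 6 highest there and the most abundant, Maob, at 12.8 RPKM against a mean of 10.4, but the other mice did not follow it: mice 9 and 10 were both at -0.25 on it with monoaminergic values of -1.51 and 0.22, and mouse 11 at 0.22 with -0.11. All 18 and 13 genes had counts in every mouse, and regional regulation of the same genes stays open. The sources used here do not describe which parts of the brain were taken, so these levels may not be those of a whole brain.

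Mice 7 and 11 stood at opposite ends of the first principal component. The GC and length trend was strong (43.9% of the variance in mouse 11), but whether it was the whole cause is not decided. Once it was removed, 79.42% of their distance was kept. That distance lies on a component refitted to the remaining values. Noise of single genes, which the trend cannot take up, also adds to it. A preference for adenine-rich transcripts in the library of mouse 7 is a candidate explanation for part of what remains: median deviations of protein-coding genes differed by 0.28 (bootstrap interval over genes 0.26 to 0.30) between the highest and lowest adenine minus thymine bins, and by -0.26 in mouse 11. The larger library of mouse 11 stays open, because thinning all libraries to the smallest total kept 99.97% of its GC gap but thinning preserves relative levels and could hardly have done otherwise. Library preparation and the animals cannot be separated here, as each mouse has 1 library.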

How the results depend on the processing

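Of the alternative settings in this part, recomputed RPKM and its comparison with deposited levels, protein-coding genes, lists without shared genes and trend removal were chosen after the data were examined and the rest before. No paired analysis was possible because the labels give 1 group only. The number of variable genes was 0 under the other scalings, the higher count filter, the non-robust prior, limma, trend removal and each left-out mouse. It was 230 without a count filter, none of them with a mean count under 10, and 2 with trends removed and mouse 11 left out. DESeq2 marked 49 by its dispersion outlier rule, which is not an adjusted p. The fitted F distribution had 31.4 prior degrees of freedom without the count filter and 6.05 in the main fit. The cause of the differing numbers was not tested. The coefficient of variation ranged from 0.167 (without mouse 11) to 0.258 (without mouse 8) when a mouse was left out, and was 0.170 with trends removed, 0.161 for protein-coding genes with trends removed and 0.146 with trends removed and mouse 11 left out. Between 14 and 20 lists reached percentile 99 under the other settings, 12 to 17 of them among the 17. Mitochondrially encoded genes took 2.45% of counts without their ribosomal RNAs, by construction. Counts without length correction reversed the log2 ratios of Drd2 to Drd1 (-0.81), C1qa to C4b (-2.33), Apoe to Clu (-0.38), Per2 to Arntl (0.15) and Sod1 to Sod2 (-0.68), as transcripts differ in length, and moved 9 others beyond 1 SD. Of 22 pairs, 17 to 19 had 1 sign in all mice under every setting. Between 11778 and 15565 genes were detected under other RPKM limits. All 1188 levels recomputed for 198 genes stayed within 1 SD, which leaving out a mouse gives by construction. With trends removed the deviation of mouse 11 reversed for Olig1 (-0.020), Ckb (-0.056) and mt-Cytb (0.23). Of the 24 genes and ratios with 1 mouse far from the others, 21 passed after TMM scaling, 10 with trends removed, and 8 and 5 on a log2 scale. Depth limits genes below about 10 counts.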

Other observations

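The tests on glial activation lists in this part were chosen only after the results were seen, and so were the genes named in the next 2 paragraphs. The 9 Hox genes of the brainstem list had 17, 31, 0, 0 and 5 counts in mice 7 to 11. Slc6a5, the glycine transporter of inhibitory neurons in the brainstem and spinal cord, had 1.42, 3.31, 0.337, 1.32 and 0.326 RPKM. Cnpy1, which DESeq2 also marked as variable, had 2.35 RPKM in mouse 10 and 0.0913 to 0.604 in the others.

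Golga4, Golgb1, Ranbp2, Akap9, Rb1cc1 and Upf2 had their highest level in mouse 7 and their lowest in mouse 11. The Golgi coiled-coil genes Golga4 and Golgb1 had 24.0 and 19.2 RPKM in mouse 7 and 4.93 and 3.89 in mouse 11. The nuclear pore gene Ranbp2 had 26.0 and 4.41 RPKM, the centrosomal anchor gene Akap9 9.69 and 1.81, the autophagy gene Rb1cc1 11.6 and 2.35 and the nonsense-mediated decay gene Upf2 17.0 and 3.15. None passed edgeR's threshold with the trends removed (adjusted p from 0.596 to 0.812). DESeq2, with the trends kept, marked each of these genes, and also Pcsk1n, as a dispersion outlier. Pcsk1n, an inhibitor of neuropeptide processing, went the other way, with 225 RPKM in mouse 11 and 40.0 to 67.3 in the others.

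Some mitochondrially encoded genes had almost no counts. The cytochrome oxidase subunits mt-Co2 and mt-Co3 and the complex I subunits mt-Nd3 and mt-Nd4l had 0 counts in all 5 libraries, and mt-Atp6 a mean of 0.2. Of their 50-base stretches, 100%, 99.9%, 98.0%, 98.8% and 99.5% also occur in annotated nuclear transcripts, against 0% for mt-Cytb and mt-Nd1, which had 3510 and 2719 RPKM. In between, mt-Co1 and mt-Nd4 had 51.1% and 62.2% of their stretches in nuclear transcripts, at 4293 and 1341 RPKM. The nuclear copies of mt-Co2 and mt-Co3, Gm28661 and Gm28437, lie on chromosome 1 from 24614885 to 24615565 and from 24613189 to 24613971 and had means of 1.6 and 1.8 counts. Those of mt-Nd3, mt-Nd4l and mt-Atp6, Gm28438, Gm10222 and Gm10925 on the same chromosome, had means of 187, 0.2 and 0.6 counts. mt-Atp8 also had 0 counts, with 0% of its stretches found in nuclear transcripts. Only annotated transcripts were searched, so a copy in unannotated nuclear sequence would have been missed. The mitochondrial levels and share of counts above are therefore incomplete, and the levels of mt-Co1 and mt-Nd4 may be too low.

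The complement, MHC class I, disease-associated microglia and reactive astrocyte lists differed between the mice. A GC and length trend as the only cause is argued against, since 4 of the 4 lists stayed at or above percentile 99 without it. A contribution is not excluded, because the random lists were corrected in the same way. The SD went from 0.44 to 0.33 for MHC class I and from 0.30 to 0.23 for complement. It went from 0.31 to 0.29 for disease-associated microglia and from 0.34 to 0.33 for reactive astrocytes. The SD of the homeostatic microglia list was 24.99% of that of the disease-associated list, the only 1 of the 4 compared with it. This does not decide whether numbers of microglia differed. With the trends removed the homeostatic list was also lowest in mouse 9, at -0.13 against 0.020 to 0.053 in the others. Residual blood in the samples may contribute: the disease-associated microglia and erythroid lists ordered 9 of 10 pairs of mice the same way, but Hba-a1 had 12.9 to 62.0 RPKM in all mice and an order alone does not show that blood carried these genes. Leukocytes carried by residual blood cannot be told apart from other causes, because the neutrophil and monocyte list ordered 6 of 10 pairs the same way and rests on 5 measured genes. No biological explanation other than cell numbers was tested, as there is 1 group.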
